A study of Mus musculus with 4 samples.

How the data were processed

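Gene expression was measured in embryoid bodies (EBs, aggregates in which embryonic stem cells begin to differentiate) made from R1, a mouse embryonic stem cell line. Per the labels, feeder-depleted cells were differentiated for 18 h without LIF, the cytokine that keeps them undifferentiated, in EB medium alone, with DMSO, with 1.88 µM GSK-J5 or with 1.88 µM GSK-J4. Total RNA was taken from trypsin-dissociated EBs, and 100 ng was amplified, labelled with biotin and hybridised to Affymetrix arrays. Each treatment has 1 array, 4 in all, and each array was assigned to its treatment from the treatment label.

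The deposited table holds log2 expression values made by the authors with RMA in Affymetrix Expression Console 1.2.1.20, per the submitters' processing notes. RMA corrects background, brings the arrays to a common distribution of intensities and summarises the probes of a probe set. The log base is not given in the sources used here and was inferred from the range of the values, 2.20 to 14.48, so every fold below rests on base 2. Values carry 2 decimals. No scanner files were used here, so background and detection could not be examined, and the number of arrays limits the precision. The array medians over all 41345 probe sets were 6.63 (medium), 6.65 (DMSO), 6.64 (GSK-J5) and 6.64 (GSK-J4).

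Probe sets were named from the platform annotation table, which can be old. It listed 25335 of the 41345 probe sets: 23521 had a single gene symbol, 1814 had several, and for 16010 no gene was listed there. Symbols were compared through gene identifiers with a RefSeq table of the GRCm38.p6 assembly, and 0 needed an update. That table served for names only. No genomic positions are given because the build behind the arrays is not given in the sources used here. Probe sets without a single symbol stayed out of every comparison. For the 1082 genes with several probe sets the brightest on average was taken, leaving 22180 genes. A gene was counted only if its mean over the 4 arrays reached the 40th percentile of these genes (6.59), which 13308 genes did.

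With 1 array per treatment there is no spread between replicates of a treatment, so the comparisons between arrays carry no p-value. The limma alternative below takes the 3 controls as replicates of each other, which gives it 2 residual degrees of freedom. Differences are described by rules of size. A gene counts as higher (or lower) in GSK-J4 when it lies at least 1.5-fold, 0.585 on the log2 scale, above the highest (or below the lowest) of the medium, DMSO and GSK-J5 arrays; this distance to the nearest control is called the margin. The same count with each other array in the place of GSK-J4 gives the background. For pairs of arrays the rule is a 2-fold difference. The rules, the 31 gene lists, the rule for naming genes and the alternatives were chosen before the data were examined. Added afterwards were a background count in which each control is set against the other 2 controls only, the set of mitochondrially encoded genes, rescalings of that set and of list medians for GSK-J5, and the tests of feeder fibroblast RNA and of a general unfolded protein response.

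For each list the median log2 difference over all measured members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. Genes of a list can vary together, which random lists do not, so the percentile only describes these arrays. The lists were KDM6 and PRC2 genes, other JmjC histone demethylases, p53 targets, DNA damage signalling and repair, naive and general pluripotency, formative and epiblast, mesendoderm and primitive streak, primitive and visceral endoderm, neuroectoderm, trophoblast, 2-cell-like, germ line, ATF4 and amino acid response, endoplasmic reticulum chaperone and unfolded protein, NRF2 antioxidant, metal and iron response, hypoxia, sterol synthesis, heat shock, S phase, G2 and mitosis, apoptosis, Hox, WNT targets, Nodal and BMP targets, FGF-ERK and immediate early, feeder fibroblast, blood and endothelial, replication-dependent histone, control housekeeping, and cytosolic ribosomal protein genes. A gene may be on several lists.

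Named genes are the 12 highest and 12 lowest by margin in GSK-J4; the 3 highest and 3 lowest further ones by GSK-J4 minus GSK-J5; the 5 highest and 5 lowest by GSK-J5 minus DMSO; the 4 highest and 4 lowest by DMSO minus medium; Kdm6a, Kdm6b, Uty, Ezh2, Eed and Suz12; and from each list up to 4 counted members per direction, or the 2 with the largest absolute GSK-J4 minus GSK-J5 difference where none was counted. Symbols of unnamed transcripts were passed over. Any other gene is named as chosen after its values were seen.

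Alternatives were no filter, a filter at the 60th percentile, median centring, repeated quantile normalization, loess against mean intensity (span 0.3), the median over a gene's probe sets, another fold, leaving out each control array, another reference or the mean for list medians, and limma with the 3 controls taken as a single group. The rule of size was tested on data simulated for GSK-J4 against 3 controls over 13308 genes, of which 200 were changed. Each size of change was given to an equal part of these 200. The rule counted 6% of genes changed by 0.5 on the log2 scale, 98% of those changed by 1 and 100% of those changed by 1.5. It counted 0 of 13108 unchanged genes. All simulated arrays had random noise of the size seen among the controls and no culture or array effect. The simulation therefore says nothing about such an effect. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.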

Results

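Expression was profiled in R1 embryoid bodies after 18 h of differentiation in medium, DMSO, GSK-J5 or GSK-J4, with 1 array for each treatment. GSK-J4 is a cell-permeable ethyl ester that releases GSK-J1, an inhibitor of the KDM6 histone demethylases, which remove the repressive methyl mark that PRC2 places on histone H3. GSK-J5 is the matching ester of GSK-J2, a pyridine regioisomer of GSK-J1 with little activity against these enzymes, and served as the control compound at the same dose of 1.88 µM. The series asks whether blocking KDM6 elicits a DNA damage response while stem cells differentiate; arrays of self-renewing cells were not analysed here. No difference below has a replicate check.

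Embryoid bodies in GSK-J4 carried higher transcript levels of p53 target genes and of ATF4 and amino acid response genes than the controls, and lower levels of formative and epiblast genes. B4galnt2, a glycosyltransferase, read 9.62 in GSK-J4 against 6.33 to 6.43 in the 3 controls. Niban1, a stress-responsive gene, lay 7.31-fold above the nearest control and Nupr1, a stress-induced transcriptional regulator, 5.66-fold. At the other end Lef1, a transcription factor of the WNT pathway, read 8.19 against 9.84 to 9.94, 3.14-fold below the nearest control, and the growth factor gene Fgf5 read 7.23 against 8.66 to 8.83.

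Of the 13308 genes counted, 294 (2.21%) were higher in GSK-J4 than in all 3 controls by at least 1.5-fold and 112 (0.84%) were lower. The same rule gave 1 higher and 0 lower genes for the medium array, 2 and 1 for DMSO, and 0 and 0 for GSK-J5. With the GSK-J4 array set aside, each control against the other 2 controls gave at most 5 genes in both directions together. Among the 12 highest were further Trib3, a pseudokinase (margin 2.02), Inhbe, a subunit of activin E (2.02), Cd80, a ligand for T cell costimulation (1.95), Plk2, a polo-like kinase (1.84), Ddit4, an inhibitor of mTORC1 (1.84), and Ddit3, which encodes CHOP (1.76). Aldh1l2, a mitochondrial folate enzyme, Btg2, an antiproliferative gene, and Arhgef2 had margins of 1.59, 1.56 and 1.52. The controls of B4galnt2 (margin 3.19), of Inhbe (6.10 to 6.28) and of Trim66, named below, lay under the filter level of 6.59 and were not shown to be above background, so the sizes and ranks of these 3 are not exact.

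The 12 lowest also held Car4, a membrane-bound carbonic anhydrase (margin −1.58), the olfactory receptor gene Olfr307 (−1.53), ND3, a mitochondrially encoded subunit of respiratory complex I (−1.50), and the kallikrein gene Klk1b24 (−1.43). Nlrp9b (−1.22), Vrtn (−1.18), the histone H2A gene H2ac1 (−1.10), the zinc finger gene Bcl11a (−1.09), the retinoid receptor gene Rxrg (−1.08) and the potassium channel gene Kcnj3 (−1.02) followed. A second probe set of Bcl11a lay within the range of the controls, and that of Kcnj3 had a margin of −0.47. In GSK-J4 Olfr307 and Klk1b24 read under the filter level and were not shown to be above background, so their sizes and ranks are not exact either.

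**Figure D1:**
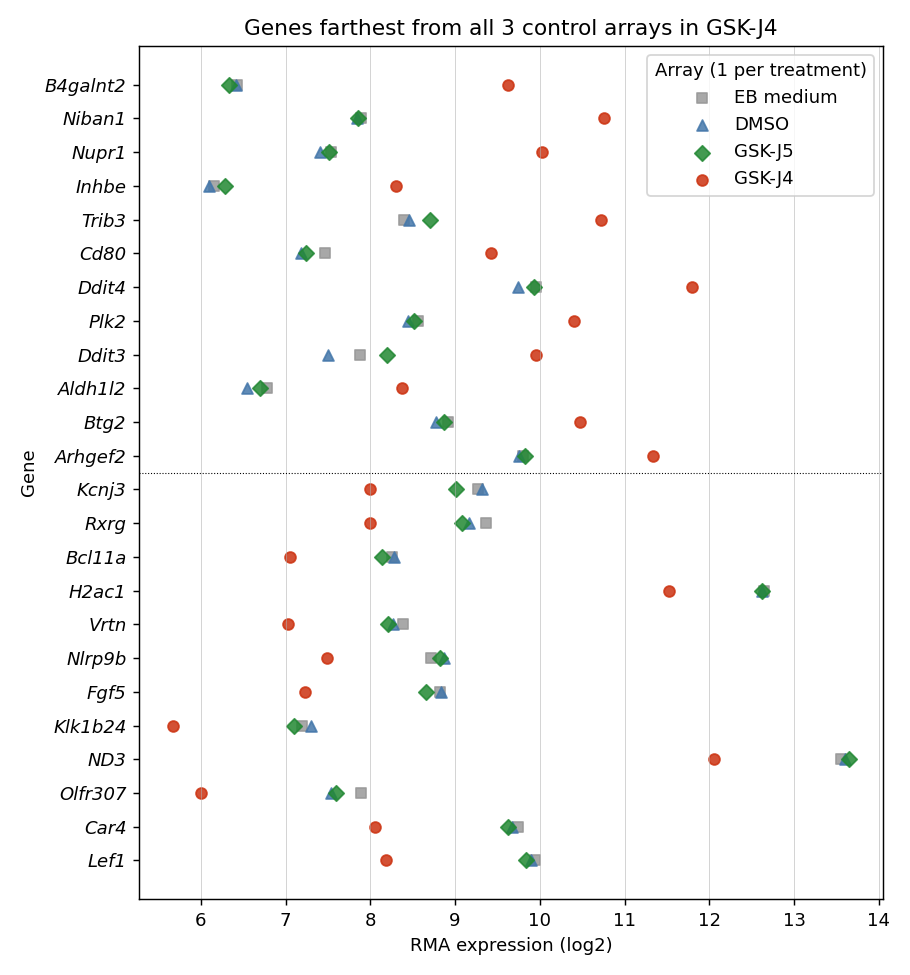
Expression (RMA, log2, horizontal axis) of the 12 genes farthest above and the 12 farthest below all 3 control arrays in GSK-J4, 1 point per array. The GSK-J4 point of each gene lies outside its control points, which span from 0.02 (H2ac1) to 0.70 (Ddit3).

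Transcripts of p53 target genes were higher in GSK-J4 as a group. Of the 40 list members that passed the filter, 22 were higher than all 3 controls by 1.5-fold and 0 lower, and 39 of the 41 measured lay above all controls by some amount. Among the highest were Cd80, Plk2, Btg2 and Trp53inp1, a p53-induced nuclear protein gene that read 12.45 against 11.18 to 11.25. Chosen after the values were seen, Cdkn1a, the p21 cell cycle inhibitor, read 11.83 against 10.75 to 10.80, and Mdm2, the ubiquitin ligase for p53, 12.03 against 11.19 to 11.25. The median GSK-J4 minus GSK-J5 difference was 0.73, above all 10000 matched random lists, and it was 0.73 against DMSO and 0.67 against medium. Between GSK-J5 and DMSO the median was 0.06, and between DMSO and medium −0.06. On the same arrays the feeder fibroblast list had a median of −0.15 and the housekeeping list −0.07.

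The list of DNA damage signalling and repair genes showed no such shift. None of the 45 measured was counted in either direction, and the median was −0.03, at percentile 12.39 of the random lists, and 0.00 after median centring. The members farthest from GSK-J5 were Prkdc, the catalytic subunit of DNA-dependent protein kinase (0.64), and Ogg1, an oxidised guanine glycosylase (0.44). Some repair genes are on the p53 list instead, among them Polk (margin 1.04), Ercc5 (0.68) and Xpc (0.20), named after their values were seen. Transcript levels do not show how active signalling proteins are, so these values do not decide whether a DNA damage response took place. Among apoptosis genes, 3 of 24 were higher and 0 lower: Bbc3, which encodes PUMA (margin 1.03), Apaf1, the apoptosome scaffold (0.87), and the death receptor gene Tnfrsf10b (0.73). All 3 are also on the p53 list. The median of the apoptosis list was −0.04, at percentile 16.81, and 0.03 against DMSO (percentile 52.52).

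Genes of the ATF4 and amino acid response formed the other group that was higher in GSK-J4. Of the 46 passing the filter, 20 were higher and 0 lower, and 46 of the 48 measured lay above all controls. Among members that passed, Nupr1, Trib3, Ddit4 and Ddit3 were the farthest, with margins of 2.50, 2.02, 1.84 and 1.76. The cystine transporter gene Slc7a11, named after its values were seen, had a margin of 1.78 but was too dim to be counted. Its controls, at 5.04 to 5.49, lay under the filter level, so this margin is not exact. Chosen after the values were seen, Atf4 itself read 9.91 against 9.28 to 9.35, Chac1, a glutathione-degrading enzyme, 10.54 against 9.11 to 9.44, and Pck2, the mitochondrial PEP carboxykinase, 11.33 against 9.68 to 10.12. The median GSK-J4 minus GSK-J5 difference was 0.55, above all 10000 random lists, and 0.69 against DMSO. Sesn2 is the single gene shared with the p53 list; the p53 and ATF4 lists together held 41 of the 294 higher genes (13.9%). On these arrays the feeder fibroblast median was −0.15, as above, and the ribosomal protein median 0.02.

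Other stress lists moved less. Herpud1, a gene of endoplasmic reticulum protein degradation, was the only counted member of 23 chaperone and unfolded protein genes (margin 0.69), and the list's median was −0.05 (percentile 13.29). Of 19 NRF2 antioxidant genes, Ephx1, an epoxide hydrolase (1.19), and Hmox1, heme oxygenase (0.67), were higher, with a list median of 0.03 (percentile 83.71). Ephx1 is also on the p53 list, and Slc7a11, too dim to be counted, is on the NRF2 list as well as the ATF4 list. Hmox1 and the zinc transporter gene Slc39a10 (−0.81) were the counted members of 11 metal and iron genes, whose median was 0.00 (percentile 59.39). None of 17 heat shock genes was counted; Hspa1a and Hspb8 differed most from GSK-J5, and the median was −0.01 (percentile 50.78), or 0.02 under loess and median centring.

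**Figure D2:**
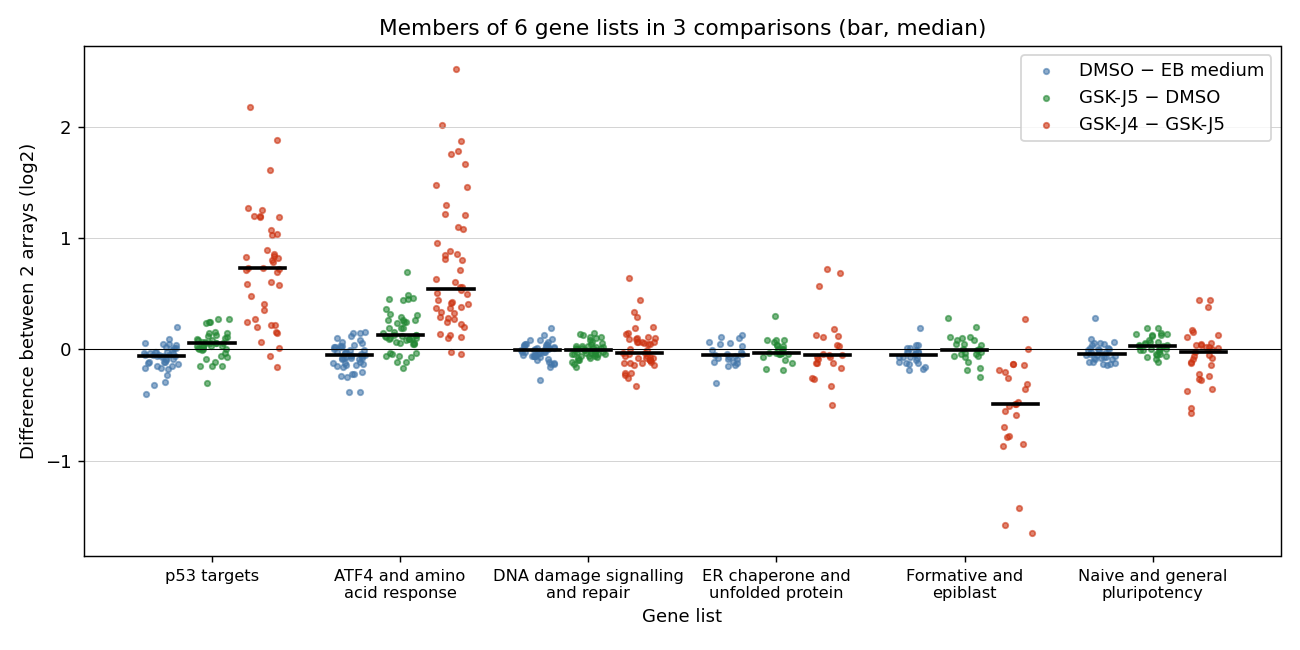
Differences between 2 arrays (log2, vertical axis) for every measured member of 6 gene lists, 1 point per gene, with the median as a bar, for DMSO minus medium, GSK-J5 minus DMSO and GSK-J4 minus GSK-J5. The GSK-J4 medians are 0.73 for p53 targets, 0.55 for the ATF4 list and −0.49 for formative genes, and −0.03 for DNA damage and repair genes.

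Formative and epiblast genes, many of which embryonic stem cells raise as they leave the naive state, were lower in GSK-J4. No array from before differentiation was analysed, so a rise of these genes over the 18 h was not measured. By the rule of size 8 of 24 were lower and 0 higher, and 21 lay below all controls. Lef1, Car4 and Fgf5 were the lowest, followed by Pou3f1, a POU transcription factor that read 8.45 against 9.24 to 9.49. Chosen after the values were seen, Dnmt3b, a de novo DNA methyltransferase, read 11.30 against 12.07 to 12.18. Nodal was the only member above all controls (11.40 against 11.09 to 11.22). The median was −0.49, below all 10000 random lists, and −0.45 against DMSO, beside 0.00 for GSK-J5 minus DMSO. The feeder fibroblast list, at −0.15, and the housekeeping list, at −0.07, were lower by less.

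Genes of naive and general pluripotency had a median of −0.02 (percentile 46.3), with 0 of 30 counted, and the sign turned under median centring (0.01), quantile normalization (0.01) and loess (0.02). Gbx2 (−0.57) and Dppa3 (−0.53) differed most from GSK-J5; a second probe set of Gbx2 had a margin of −0.04. Several lineage and signalling lists were lower than in GSK-J5, though not all of them against the other controls. Mesendoderm and primitive streak genes had a median of −0.20 (percentile 0.55), and −0.12 against medium (percentile 3.02), just inside the random range. Only 19 of the 29 measured passed the filter, and among these Hoxb1 (margin −0.81) and Eomes, a T-box factor (−0.60), were lower. Hoxb1 read 6.48 in GSK-J4, under the filter level, so its margin is not exact. Hox genes had a median of −0.23 (percentile 0.25), and −0.14 under loess. This median covers 36 measured genes, of which only 12 passed the filter, so it rests mostly on dim genes. The central range of the matched random lists, −0.19 to 0.01, was itself shifted downward. Hoxb1 was the only counted member of the 12. Against DMSO the Hox median was −0.16 (percentile 8.61) and against medium −0.05 (percentile 40.05), both inside the range of random lists. WNT targets had a median of −0.21 (percentile 0.15), with Lef1 and Myc (−0.70) lower among 13; their mean was −0.33. Nodal and BMP targets had a median of −0.17 (percentile 0.14) with 0 of 17 counted; Smad6 (−0.62) and Id2 (−0.49) were the farthest from GSK-J5. The trophoblast list had a median of −0.17 (percentile 2.24) over 20 measured genes. The imprinted gene Phlda2 was lower (margin −0.65) among the 13 that passed the filter. The trophoblast median was −0.10 under loess and −0.10 against DMSO, there inside the random range (percentile 11.95).

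Neuroectoderm genes (median −0.09, percentile 20.7) had 0 of 16 counted, and their median was −0.13 against DMSO and −0.16 against medium (percentile 0.62); Gbx2 and Sox1 differed most from GSK-J5. Primitive and visceral endoderm genes (median −0.02, percentile 70.47, 0.01 under loess and median centring) had 0 of 22 counted, with Sox7 and Amn the farthest. Sox7 did not pass the filter, and Amn read 6.54 in GSK-J4, under the filter level. In FGF-ERK and immediate early genes the median was −0.07 (percentile 4.96) against GSK-J5, 0.01 against DMSO and −0.11 against medium (percentile 0.96); Fos was higher (margin 0.67) and Myc lower among 27.

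Germ line and 2-cell-like genes had small positive medians. For germ line genes the median was 0.25, with 1 of 10000 random lists as high, and Smc1b, a meiotic cohesin subunit, was the only counted member of 17 (margin 0.65, or 0.57 after quantile normalization). For 2-cell-like genes, which mark a rare totipotent-like state of embryonic stem cell cultures, it was 0.20, with 3 of 10000 random lists as high; Zfp750 was the only counted member of 13 (margin 1.19) and only 13 of the 26 measured passed the filter, with a median of 0.10 over those.

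Mitotic, sterol, hypoxia and histone genes were lower by small amounts. Of 31 G2 and mitosis genes 28 lay below all controls, with a median of −0.16 below all 10000 random lists but 0 counted; the mitotic kinase genes Plk1 (−0.50) and Aurkb (−0.40) were among those farthest from GSK-J5. S phase genes had a median of −0.06 (percentile 9.54) and 0 of 30 counted, with Tk1 and Ccne1 the farthest. Sterol synthesis genes had a median of −0.24, below all 10000 random lists, with 0 of 20 counted, Fdps at −0.59 and Dhcr7 at −0.57. Among 22 hypoxia genes Vegfa was higher (margin 1.11), while Egln3, a prolyl hydroxylase (−0.89), Bnip3 (−0.84) and the glycolytic gene Tpi1 (−0.68) were lower; the median was −0.16 (percentile 0.09). The 17 measured of 46 histone genes had a median of −0.20 (percentile 0.14), a mean of −0.12 and 0 counted. Against medium their median was −0.12 (percentile 4.77), inside the random range. H4c8, which was higher (0.78), and H1f3 (−0.44) were the farthest from GSK-J5, and both were below the filter.

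The KDM6 genes themselves differed little. Kdm6a read 12.08 in GSK-J4 against 12.03 to 12.07, and Uty, its Y-linked paralogue, 10.54 against 10.39 to 10.47. Kdm6b read 10.22 against 9.77 to 9.84, while its second probe set had a margin of 0.02. Of the PRC2 core, Ezh2 (12.44), Eed (11.57) and Suz12 (12.08) lay within 0.05 of the nearest control. KDM6 and PRC2 genes had 0 of 13 counted and a median of −0.01 (percentile 52.16), which was 0.02 under all 3 rescalings; Phf19 had a margin of −0.41. Other JmjC demethylases had 0 of 15 counted and a median of −0.01 (percentile 38.8), 0.02 under median centring and 0.00 under loess. Their median was 0.09 against DMSO (percentile 89.2) and 0.04 against medium (percentile 77.98). Kdm7a (0.63) and Kdm4a (0.42) were the farthest from GSK-J5.

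Lists of other cell types and the housekeeping and ribosomal protein lists shifted less than the p53, ATF4 and formative lists. RMA brings the arrays to a common distribution, so the housekeeping and ribosomal protein lists cannot test RNA input. Feeder fibroblast genes, at −0.15, lay at percentile 4.79 with 0 of 16 counted, and at −0.09 against DMSO and −0.10 against medium. Dcn and Thbs1 were the farthest, and both were lower, but Dcn was below the filter on all arrays. Of 7 blood and endothelial genes Laptm5 was higher (margin 1.29), and the list's median was 0.00 (percentile 79.96), −0.10 against DMSO and 0.12 against medium (percentile 98.09). Housekeeping genes lay at percentile 16.19 with 0 of 16 counted, B2m (0.44) and Polr2a (0.41) being the farthest. Cytosolic ribosomal protein genes lay at percentile 89.21 with 0 of 38 counted, and at 0.04 against medium (percentile 97.87); Rps23 (−0.58) and Rps27 (0.36) differed most.

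Set directly against GSK-J5, the isomer at matched dose and time, GSK-J4 had 110 genes higher and 19 lower by 2-fold. Neat1, the paraspeckle RNA (1.74), Apobec1, a cytidine deaminase (1.56), and Trim66 (1.55) were the highest of the genes not among the 12 highest by margin. The lowest of the genes not among the 12 lowest by margin were Rny3, a small cytoplasmic Y RNA (−1.40), Egln3 (−1.10) and Slc16a3, a lactate exporter (−1.07). Over the 13308 genes the differences had an SD of 0.289, against 0.133 between GSK-J5 and DMSO. Of the 31 lists, 14 had medians outside the central 95% range of their random lists, 4 above and 10 below, and the medians of these 14 kept their sign under all 3 rescalings. Against DMSO, GSK-J4 had 112 genes higher and 31 lower by 2-fold, and 12 lists outside the range.

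GSK-J5 differed from DMSO by 2-fold in a single gene, Tcl1b2 (−1.06), a relative of the Tcl1 oncogene. The highest genes were Ddit3 (0.70), Tob2, an antiproliferative gene (0.62), Mir423 (0.61), Rnu3a, a small nucleolar RNA (0.60), and Try4, a trypsin (0.59). Below Tcl1b2 came Unc93a (−0.75), Mir466b-2 (−0.72), the ribosomal protein gene Rps13 (−0.70) and Mir466b-3 (−0.69). Tcl1b2 and Unc93a in GSK-J5 and Mir423 and Try4 in DMSO read under the filter level, so their differences are not exact. The ATF4 list was nonetheless higher in GSK-J5 by a small amount. Its median was 0.12 against DMSO and 0.07 against medium, each above all 10000 random lists. Of its 48 measured members, 46 of which passed the filter, 34 (70.83%) lay above both. Among all 13308 genes passing the filter the share was 29.7%. Sterol synthesis genes were lower, at −0.05 against DMSO (percentile 0.90) and −0.09 against medium (percentile 0.02), with 11 of 20 below both and 0 above both. Both directions held under the 3 rescalings. In all, 6 of 31 lists lay outside their random range against DMSO, 4 above and 2 below; p53 targets (0.06), apoptosis genes (0.07) and Nodal and BMP targets (0.08) were above and heat shock genes (−0.08) below, while against medium these 4 medians were −0.04, −0.03, 0.00 and −0.02. Against medium 7 lists lay outside, 5 above and 2 below. Beside the ATF4 and sterol lists, these were Hox (0.15), 2-cell-like (0.08), replication-dependent histone (0.07) and ribosomal protein genes (0.03) above and other JmjC demethylases (−0.07) below. Without replicate arrays no interval can be given for these differences, and the small numbers do not show that GSK-J5 and DMSO act alike.

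DMSO and medium differed by 2-fold in 0 genes. The highest in DMSO were Rps13 (0.77), Grb14, a growth factor receptor adaptor (0.75), Phf11c (0.73) and Nacad (0.72), and the lowest Ly6g5c (−0.67), the kallikrein gene Klk1 (−0.65), Mir505 (−0.64) and Lrrc36 (−0.62). Grb14 and Phf11c in medium and Ly6g5c and Lrrc36 in DMSO read under the filter level. Rps13 was thus high in DMSO against both neighbours, with 8.24 on that array and 7.47 and 7.54 on the medium and GSK-J5 arrays. List medians ran from −0.09 to 0.04, and 2 of 31 lay outside the range of their random lists: Nodal and BMP targets (−0.09) and the ATF4 list (−0.05).

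**Figure D3:**
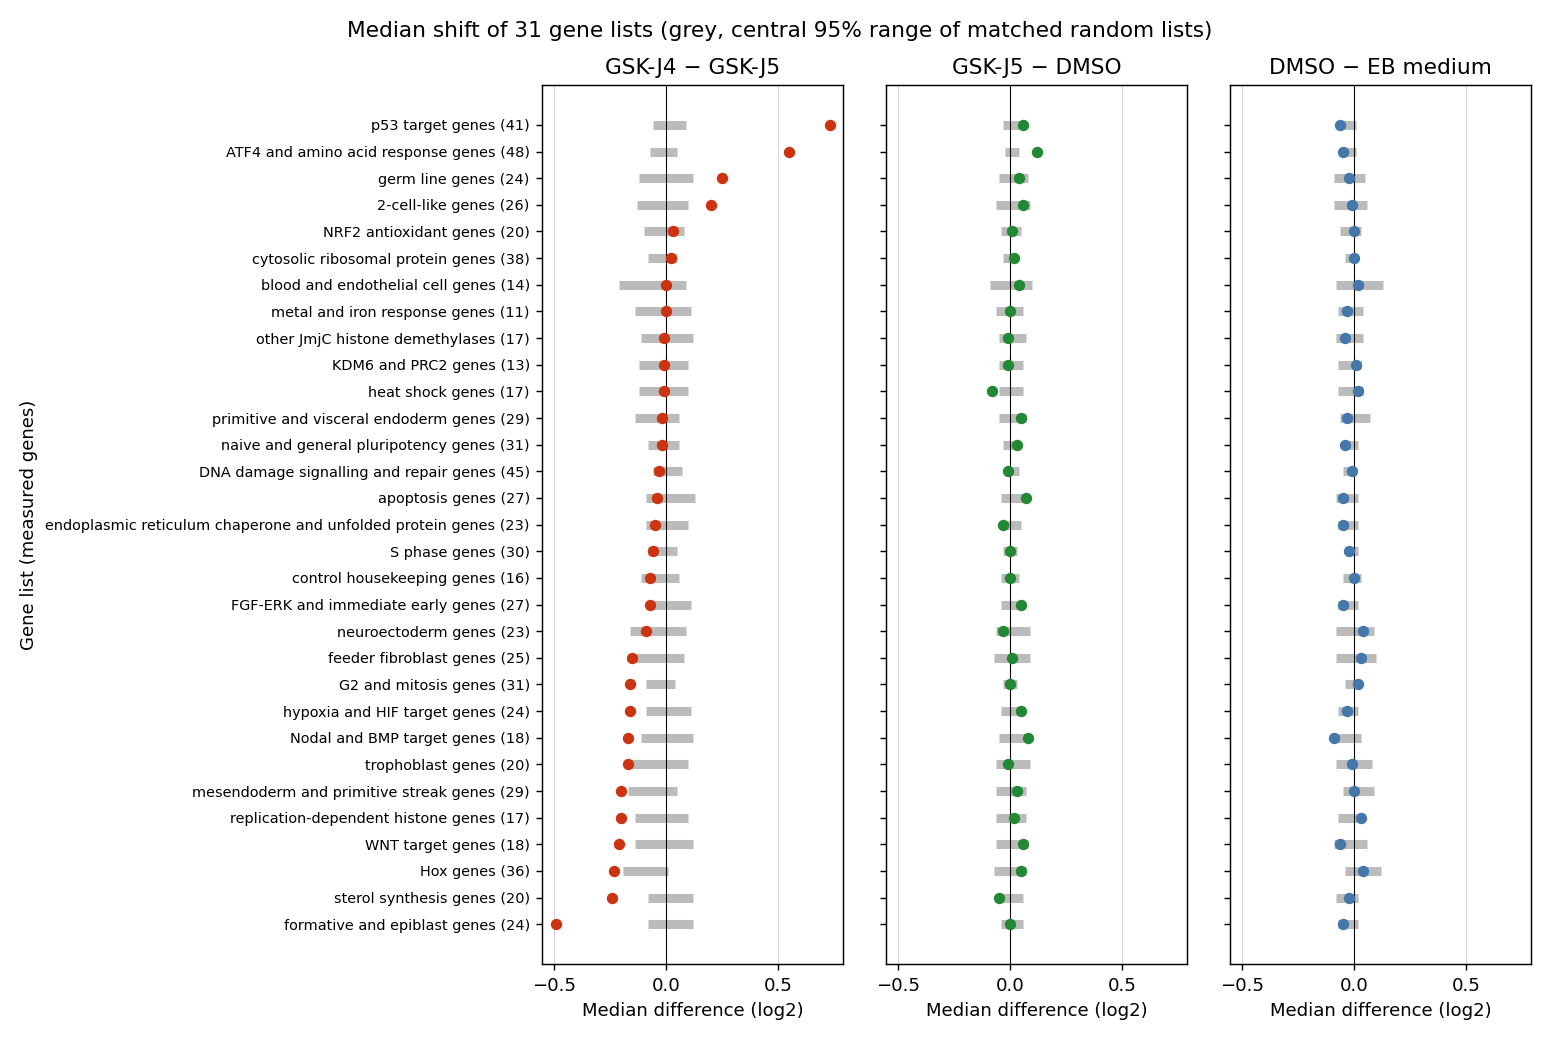
Median difference (log2, horizontal axis) of each of the 31 gene lists for GSK-J4 minus GSK-J5, GSK-J5 minus DMSO and DMSO minus medium, with the central 95% range of matched random lists in grey and the number of measured genes in brackets. The p53 (0.73), ATF4 (0.55) and formative (−0.49) lists stand farthest out in GSK-J4, and the ATF4 list (0.12) in GSK-J5.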

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

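Probe sets without a single gene symbol took no part in the comparisons above. Their counts stood above the level of the control arrays, except for those lower by 1.5-fold. Of 17824 such probe sets, 7009 passed the brightness filter. By the 1.5-fold rule 186 of them were higher in GSK-J4 than in all 3 controls, while the same rule gave 25 for medium, 22 for DMSO and 5 for GSK-J5. By 2-fold, 25 were higher in GSK-J4, against 0 for medium, 2 for DMSO and 0 for GSK-J5, and 14 were lower, against 2, 1 and 3. Lower by 1.5-fold were 63 in GSK-J4, against 29 for medium and 26 for DMSO, which did not exceed the 82 of GSK-J5. Chosen after their values were seen, probe set 17315312 read 9.33 against at most 7.33 in the controls, and 17501828 read 10.19 against at most 8.55. Probe set 17532593 read 7.26 against at least 9.96, and 17532615 read 9.06 against at least 11.58. By number, 17532615 falls between the probe sets of the mitochondrially encoded genes COX1 (17532609) and COX3 (17532617). Probe set 17532593 comes shortly before that of ND1 (17532603). What either one measures was not established. No explanation was tested for these counts.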

How the results depend on the processing

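The background of each control against the other 2 controls, and the rescalings of GSK-J5 list medians and of mitochondrial genes, were chosen after seeing the data; all alternatives listed beforehand were run. No paired analysis was possible because each group holds 1 array. GSK-J4 beyond all 3 controls, 294 higher and 112 lower, became 191 higher at the 60th percentile filter and 76 higher and 14 lower at 2-fold, by construction. Leaving out a control array gave 320 to 341 higher and 129 to 141 lower. With limma and the 3 controls as a single group, to which the lone GSK-J4 array is assumed similar in spread, 1651 genes were higher and 1180 lower at adjusted p under 0.05, and 2670 and 2106 at unadjusted p; this test has no size limit, and the spread of GSK-J4 itself was not measured. At the 60th percentile GSK-J4 had 67 higher genes against GSK-J5 and 69 against DMSO, and GSK-J5 had 0 lower against DMSO. At 1.5-fold the counts were 437 and 185 (GSK-J4 against GSK-J5), 518 and 209 (against DMSO), 7 and 16 (GSK-J5 against DMSO) and 16 and 5 (DMSO against medium). Without a filter, dim genes added calls: 33 lower in GSK-J4 against GSK-J5, 7 higher and 5 lower in GSK-J5 against DMSO, and 8 higher and 13 lower in DMSO against medium. The mean in place of the median gave 0.74 for the ATF4 list and −0.55 for formative genes, and DMSO as reference gave 0.69 for the ATF4 list; the cause was not tested. Over the other 28 lists, 160 of 224 alternative medians moved by less than the controls' own spread, 64 by more, and 0 of those outside their random range changed sign. Mean and median differed in sign for DNA damage (0.01), KDM6 and PRC2 (0.05), other JmjC (0.07), endoplasmic reticulum (0.01), heat shock (0.02) and apoptosis genes (0.12, means). Of 51 named genes past 1.5-fold, Bcl11a (−0.51, median over probe sets) and Smc1b (0.57, quantile) fell short under an alternative.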

Other observations

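The tests of feeder fibroblast RNA and of a general unfolded protein response, and the rescalings of mitochondrial genes and of GSK-J5, were chosen only after the result was seen; the others were set before it. Outside the fixed lists, several well-known genes stood apart in GSK-J4, and all named here were chosen after their values were seen. Mdm4, an inhibitor of p53, read 11.92 against 10.97 to 11.02 in the controls. Eng, a TGF-beta co-receptor, read 11.22 against at most 9.94, Abcb1b, a drug efflux pump, 10.21 against at most 8.81, the ATP-gated channel gene P2rx7 9.53 against at most 8.33, and the peptide hormone gene Adm2 9.02 against at most 7.69. Lower were Ccnd2, a D-type cyclin (9.82 against at least 10.72), Myb (9.28 against at least 10.15), Fgf15 (10.54 against at least 11.44), Wt1 (7.67 against at least 8.63) and the semaphorin gene Sema6a (7.77 against at least 8.73).

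Of 10 mitochondrially encoded genes, a set on none of the fixed lists and chosen after the values were seen, 9 lay below all 3 controls in GSK-J4. By number, the ND4L probe set (17221871) stands apart from those of the other genes (17532603 to 17532649). Whether it measures the mitochondrial transcript was not established. The median GSK-J4 minus GSK-J5 difference of the 10 was −0.24. Under each of the 3 rescalings 9 lay below. The median was then −0.21 (median centring), −0.20 (quantile normalization) and −0.18 (loess). ND3 stood out with 12.06 against 13.56 to 13.65, and the other 9 differed by −0.44 (COX3) to 0.03 (ND6). None of those 9 reached a margin of 1.5-fold. Below all 3 controls lay 35.5% of the 13308 genes counted, and 47.5% of the 139 genes with a mean of 13 or more, where most of this set lies.

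The p53 target genes were higher in GSK-J4 by a median of 0.73. A trend of signal with intensity is argued against, since the median was 0.73 after loess had removed each array's trend. RNA from remaining feeder fibroblasts is argued against too: the fibroblast list was not higher, with a median of −0.15 relative to GSK-J5. Of its collagens Col1a1 was at −0.25, Col1a2 at −0.42 and Col3a1 at 0.00, the last 2 dim and close to the filter. An effect of one culture or array per treatment cannot be told apart from the compound, because there was 1 GSK-J4 array, and an effect of KDM6 inhibition stays open and untested.

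The ATF4 and amino acid response genes were higher by a median of 0.55, and by 0.57 after loess, which argues against an intensity trend. A general unfolded protein response would raise endoplasmic reticulum chaperones. Their list's median was −0.05 with 1 of 23 counted, which argues against a general rise of these transcripts. The test was chosen after the result was seen, and it cannot speak to a response that leaves the chaperones unchanged. With 1 array in GSK-J4, an effect of one culture or array per treatment cannot be told apart from the compound. GSK-J5 showed a shift of the same sign, 0.12 against DMSO but 0.07 against medium (0.04 after median centring), and DMSO itself stood at −0.05 against medium. Whether the esters share part of the response was not tested, and neither was an effect of KDM6 inhibition.

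The formative and epiblast genes were lower by a median of −0.49, and by −0.51 after loess, which argues against an intensity trend. A delay in leaving the naive state could lower them. Of 13 naive genes 7 lay above all controls, among them Klf5 (0.44) and Tbx3 (0.44). Below all controls lay 4, Dppa3 at −0.53, which is close to the 35.5% of all 13308 genes counted. The share of all genes above all controls is not given here. The median of the naive genes was 0.04. These values do not settle whether there was a delay. One culture or array per treatment, with 1 GSK-J4 array, cannot be told apart from the compound, and an effect of KDM6 inhibition on these genes stays open and untested.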
